A study of Mus musculus with 16 samples.

How the data were processed

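The study measured RNA of NIH3T3 mouse fibroblasts on 2-colour cDNA arrays, with treated and untreated cells of one line in the 2 channels of each array. Samples were grouped by the titles and source names of the labels into Erbb2-transfected cells at 10 µM azacytidine (8 arrays), the same cells at 5 µM (4 arrays) and untransfected cells at 10 µM (4 arrays). The treated RNA was in Cy5 on 50% of the arrays of each group and in Cy3 on the others, by the dye label of channel 1. For the untransfected cells both channels of each array carry the same dye label, so the channel 1 label was used there and may be wrong. The label protocol, which speaks of organs and a reference pool of animals rather than of cell lines, was not used for the grouping. The title of the first untransfected array has no replicate number.

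The deposited values are log ratios of the 2 channels, read here as log2, and were centred near 0 by the authors, with medians per array from -0.03 to 0.05. The log base is not stated and was inferred from the highest values. Each array held between 72 and 167 cells with 1 identical value between 15.4 and 16.6, far above the other ratios, which ended at 7.94. These 1755 cells of 325680 were read as placeholders and set to missing, beside 38737 cells without a value, and this reading is an inference. Image analysis, background correction, normalization and the reason for missing cells are not given in the sources used here. Signal intensities are not in the files, so signal over background is unknown. An array gave between 16153 and 18507 ratios, and the number of arrays per group limits the precision. No column of per-sample values was left unused.

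The direction of the ratios is not stated. By a rule set before the data were examined, arrays whose dyes were exchanged were compared within each group. The mean Pearson's r over probes was -0.0172 for pairs of arrays with opposite dye labels and 0.0621 for pairs with the same label, averaged over the 3 groups. By group, opposite labels gave 0.00388 in Erbb2 cells at 10 µM, -0.00267 at 5 µM and -0.0529 in untransfected cells, so the negative average of Pearson's r came mostly from the group whose labels are doubtful. Same labels gave 0.0257, 0.0516 and 0.109. Spearman's rho for opposite labels was -0.00313, -0.0139 and -0.129, and for same labels 0.0611, 0.115 and 0.179. By that rule the values were taken as dye ratios, Cy5 over Cy3, and the arrays with the treated RNA in Cy3 had their sign turned. The rule cannot exclude ratios already turned to treated over untreated, since dye bias would also lower the correlation between opposite labels.

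Probes were kept with a value in at least 3 arrays of each group of 4 and at least 6 arrays of the group of 8, with at least 1 array of each dye arrangement. This left 14813 of 20355 probes. Probes with exactly 1 gene symbol were averaged by gene, which joined 2 or more probes for 1879 genes, and probes with no symbol or several stayed single, giving 12420 features. Symbols came from the platform annotation and were checked by Entrez Gene ID against the mouse reference, which held 13994 of the 14030 probes with 1 symbol and changed 0 symbols. Genomic positions of the probes are not in the files and are not given.

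The fit used limma 3.58.1 in R 4.3.3, with tables read by version 1.17.8 of data.table. All 16 arrays entered one linear model with a coefficient for each of the 3 groups and a shared term for the dye of the treated RNA, followed by eBayes. Each group was tested against 0, and 2 contrasts were tested, 10 µM minus 5 µM in Erbb2 cells and Erbb2 minus untransfected cells at 10 µM. A feature passed with a Benjamini-Hochberg adjusted p under 0.05 over all features. The dye term itself passed for 0 features, with 1000 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0855. Had the values been turned before deposit, that term would hold the drug response and the group values the dye bias. No other tool was run. All tests were two-sided.

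Gene lists fixed before the data were examined, 20 with at least 5 measured members, were tested with limma's camera with an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, for which missing cells took their fitted values. Counts adjusted over the list alone are given beside those over all features. Named genes followed a rule fixed at the same time. In each treated group it took the 10 highest and 10 lowest genes past the threshold with one sign on every array. It added up to 4 members of each list past the threshold, the 5 highest and 5 lowest of each contrast, or the 10 smallest p where fewer than 5 passed, and 7 genes named whatever their value. Genes named outside that rule in the closing section were chosen after their values were seen.

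The procedure was tested on simulated data with the same missing cells, with 50 features seeded at each size. At a log2 change of 1 it recovered 21 features in the 10 µM Erbb2 group, 16 at 5 µM and 9 in the untransfected group, and at a change of 2 it recovered 41, 31 and 32. False calls were 9 of 123, 5 of 97 and 8 of 88. Alternatives covered centring and scaling of arrays, filters, single probes, dye terms, fits on fewer groups, robust and weighted fits, thresholds, unturned values, a replicate block and leaving out each array. Chosen after the data were examined were keeping the placeholder values, leaving out the 3 widest arrays, and turning the untransfected arrays.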

Results

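Azacytidine, a cytosine analogue that is built into nucleic acids and traps DNA methyltransferases, was tested on NIH3T3 cells, an established mouse fibroblast line, with and without a transfected Erbb2 receptor tyrosine kinase oncogene. Each of the 16 arrays set RNA of treated cells against RNA of untreated cells of the same line, on cDNA probes read in 2 dyes. Erbb2-transfected cells were measured at 10 µM on 8 arrays and at 5 µM on 4 arrays, and untransfected cells at 10 µM on 4 arrays, with the dyes exchanged on 50% of the arrays. An array gave between 16153 and 18507 ratios from 20355 probes, and after filtering 12420 features were compared, of which 7832 carried a gene symbol. The interquartile range of the log2 ratios ran from 0.71 to 1.36, widest on arrays 6, 3 and 5 of Erbb2 cells at 10 µM, and the number of arrays limits the precision.

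Values are log2 ratios of treated over untreated cells, and ± is the standard error of the value fitted by limma over n arrays. Which channel was the numerator is not stated, so every direction below is the likely one, based on reading the deposited values as Cy5 over Cy3. Were they Cy3 over Cy5, every sign would turn, and with no array turned for its dye 2, 0 and 4 features passed in the groups in place of 157, 26 and 339. Were they treated over untreated already, the group values would hold dye bias in place of the drug response, which the array correlations cannot exclude. The 4 arrays of untransfected cells carry a further doubt, since both channels of each array have the same dye label. If the treated RNA was in the other dye there, all signs of that group alone would turn. The p-values measure the spread between arrays. Untreated RNA is part of each ratio, so the spread of the control cells enters only as far as that RNA differed between arrays. The labels do not say whether arrays of a group came from separate cultures.

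The first comparison asked what 10 µM azacytidine changed in Erbb2-transfected cells (n = 8). Cd5, a lymphocyte surface receptor (Entrez Gene 12507), rose by 1.29 ± 0.10, or 2.45-fold. Apaf1, the scaffold of the caspase-activating apoptosome (11783), rose by 1.15 ± 0.10, the homeobox gene Hoxb1 (15407) by 1.18 ± 0.11, and Psap, the precursor of the lysosomal saposins (19156), by 0.97 ± 0.10. Ribosomal protein genes fell as a group, with a median of -0.39 over 53 measured members, of which 18 passed as lower and 0 as higher. Genes of glycolysis and hypoxia also fell, with a median of -0.36 over 20 members and 3 past the threshold, all lower. Sparc, a collagen-binding matrix protein (20692), rose by 0.68 ± 0.11 and was the extracellular matrix gene past the threshold, out of 31 measured.

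Of the 12420 features, 157 passed an adjusted p under 0.05 in limma, 50 higher and 107 lower, and 81 of them carried a gene symbol. The value with the greatest size among named genes was that of Tmem86a, a lysoplasmalogenase (67893), at 2.60 ± 0.38 over 7 arrays. Its adjusted p from limma was 0.0027. Tmem86a ran from 0.566 to 1.5 with the treated RNA in Cy5 and from 2.248 to 5.643 with it in Cy3. At 5 µM it had -0.71 and -0.394 with the treated RNA in Cy5, and 1.348 and 1.249 with it in Cy3. The size of its rise therefore depended on the dye. Further genes that rose were the transcription factor Cebpd (1.18 ± 0.17), Hyi, a hydroxypyruvate isomerase (1.11 ± 0.10), the tetraspan membrane protein gene Lhfpl2 (0.99 ± 0.12), Zfp36, which speeds the decay of AU-rich messenger RNAs (0.96 ± 0.15), and the basement membrane proteoglycan gene Agrn (0.90 ± 0.14). Genes that fell included Ctdspl2, a phosphatase-like gene (-1.20 ± 0.26, n = 7), the hydroxysteroid dehydrogenase Akr1c18 (-1.09 ± 0.12) and its relative Akr1e1 (-0.78 ± 0.12), Klhl21, a cullin adaptor (-0.89 ± 0.17), and phosphoglucomutase Pgm1 (-0.80 ± 0.15). The Hsp70 cofactors St13 (-0.94 ± 0.16) and Dnaja1 (-0.89 ± 0.19) fell as well. Each of the 28 named genes that passed had one sign on every array with a value, except Pkm with 7 of 8 arrays.

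The ribosomal members with the greatest fall were Rps16 (-0.83 ± 0.18), Rpl5 (-0.81 ± 0.10), Rpsa (-0.68 ± 0.12) and Rps14 (-0.64 ± 0.09), and the shift of the list had an adjusted p of 2.64e-25, or 1.56e-10 with an estimated correlation. Adjusted over the list alone, 29 ribosomal genes were lower and 1 was higher. Elongation factor Eef2, which moves the ribosome along the message, fell by 0.78 ± 0.17. In glycolysis, aldolase Aldoa (-0.69 ± 0.10), pyruvate kinase Pkm (-0.69 ± 0.13) and Gapdh (-0.53 ± 0.10) fell, and the list had an adjusted p of 0.000633, or 0.00641 with an estimated correlation. Adjusted over the list alone, 5 glycolysis genes were lower and 1 was higher. The replication clamp Pcna (-0.48 ± 0.09) was the 1 of 33 cell cycle genes that passed, and the stress transcription factor Atf4 (-0.41 ± 0.09) the 1 of 22 genes of the integrated stress and unfolded protein response.

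The other 18 lists did not pass at 10 µM, with adjusted p from 0.228 to 0.953 and medians from -0.12 to 0.19. They were DNA methylation machinery, imprinted genes, germline genes, interferon response, MHC class I antigen processing, p53 targets, cell cycle, integrated stress and unfolded protein response, extracellular matrix, contractile and smooth muscle, skeletal muscle, adipocyte, epithelial, blood and immune cells, ErbB and MAPK signalling, tumour suppressors with promoter methylation in cancer, oxidative stress and metallothionein, and cholesterol synthesis. Among the lists that did not pass, the median, the mean and the test differed in sign for DNA methylation machinery, germline genes, MHC class I antigen processing, extracellular matrix, skeletal muscle, adipocyte, epithelial genes and tumour suppressors. The maintenance methyltransferase Dnmt1, the enzyme azacytidine traps, had 0.28 ± 0.10 with an adjusted p of 0.295 from limma and did not pass. Neither did the cell cycle inhibitor Cdkn1a (-1.24 ± 0.54, n = 6), the MHC class I light chain B2m (0.33 ± 0.17) or the peptide transporter Tap1 (-0.00 ± 0.29). Cdkn1a ran from -2.77 to -2.55 with the treated RNA in Cy5 and had -0.67 and 2.56 with it in Cy3. Erbb2 and H19 had no probe under those symbols, and the probe of Bgn had too few values to be kept.

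Without arrays 3, 5 and 6, the 3 with the widest spread, 57 features passed, 27 higher and 30 lower, and without array 1 or without array 4 the count was 103. Fitted on its own arrays, so that the other groups did not add to the estimate of the spread, this group gave 22 features, 15 higher and 7 lower, and 33 passed a test against a 1.2-fold change, 21 higher and 12 lower. The excess of lower features among the 157 was thus not seen in every fit.

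**Figure D1:**
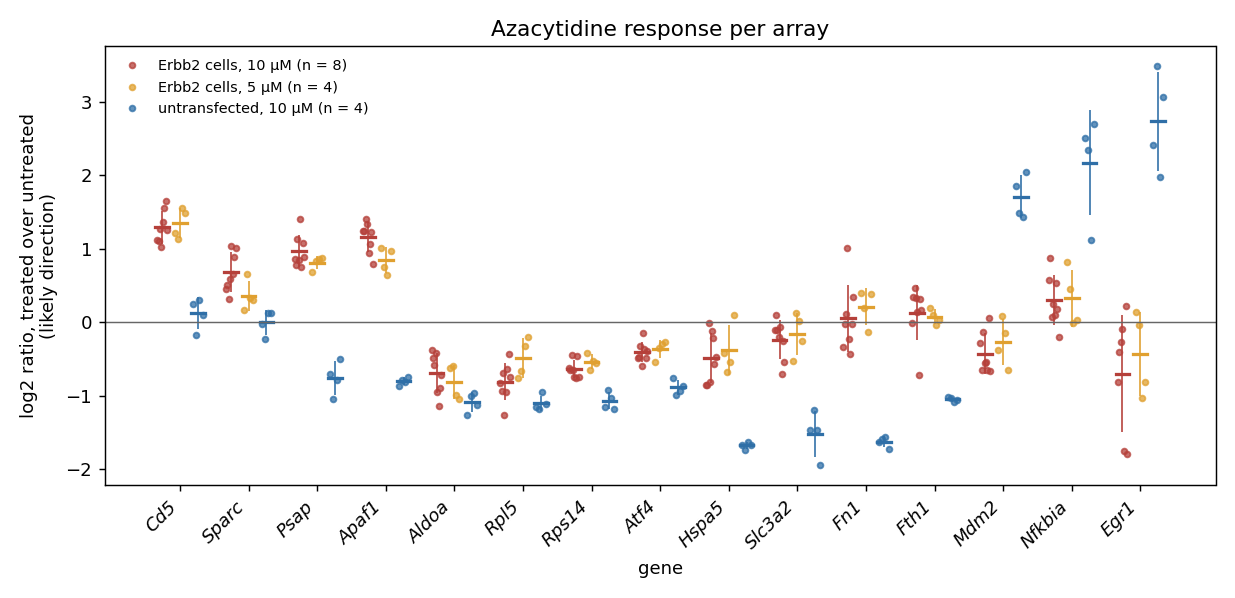
Log2 ratio of treated over untreated cells, in the likely direction, on each array for 15 genes, with a bar at the mean and a line of 1 SD on each side, for Erbb2 cells at 10 µM (n = 8) and 5 µM (n = 4) and untransfected cells at 10 µM (n = 4). Cd5 lies above 0 on each array of Erbb2 cells, Hspa5, Slc3a2, Fn1 and Fth1 lie lowest in untransfected cells, and Mdm2, Nfkbia and Egr1 lie highest there.

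The second comparison asked what the lower dose of 5 µM changed in the same transfected cells (n = 4). Cd5 again rose, by 1.35 ± 0.14, together with Hoxb1 (0.87 ± 0.15), Apaf1 (0.84 ± 0.14), Psap (0.81 ± 0.15), Lhfpl2 (0.90 ± 0.17), Hyi (0.75 ± 0.13) and Cp, the copper-carrying ferroxidase ceruloplasmin (0.95 ± 0.17). Znf41-ps, a zinc finger pseudogene (1.04 ± 0.16), Samd11 (0.99 ± 0.18) and Haus4, a subunit of the augmin complex of the spindle (0.69 ± 0.13), rose too. Aldoa fell by 0.81 ± 0.14, the ephrin receptor Ephb1 by 1.58 ± 0.28 and the zinc finger gene Zcchc4 by 0.90 ± 0.17. Ribosomal protein genes fell as a list, with a median of -0.30 over 53 members, although 0 of them passed alone, or 11 when adjusted over the list alone.

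In limma, 26 features passed, 22 higher and 4 lower, 13 of them with a gene symbol. These 13 genes had one sign on all 4 arrays, which the naming rule required of the highest and lowest genes. The ribosomal shift had an adjusted p of 1.28e-12, or 3.13e-05 with an estimated correlation. Glycolysis and hypoxia had a median of -0.24 with 1 member past the threshold, or 2 when adjusted over the list alone, and an adjusted p of 0.0159, which became an adjusted p of 0.0704 with an estimated correlation and was then lost. The other 18 lists had adjusted p from 0.189 to 0.967, and the median, the mean and the test differed in sign for DNA methylation machinery, MHC class I antigen processing, tumour suppressors and oxidative stress. Dnmt1 (0.50 ± 0.14), B2m (0.92 ± 0.24), Cdkn1a (0.07 ± 0.65) and Tap1 (-0.15 ± 0.47, n = 3) did not pass. The count fell to between 5 and 6 when any 1 of the 4 arrays was left out, and Cd5 was the 1 of the 13 named genes that passed in each of those fits. Fitted on its own arrays the group gave 0 features.

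The third comparison set the doses against each other in Erbb2 cells. In limma, 0 of 12420 features differed past the threshold, with a smallest adjusted p of 0.682, and 538 had an unadjusted p under 0.05 where chance gives 621. The 10 features with the smallest p, given here as not passing, were Znf41-ps (-1.05 ± 0.20), Ephb1 (1.83 ± 0.35), Atat1 (-1.46 ± 0.29), App (0.95 ± 0.20), Mrpl30 (2.15 ± 0.43), Haus4 (-0.71 ± 0.16), Tmco5b (-0.91 ± 0.20), Fzd3 (2.75 ± 0.62) and the unnamed probes probe8712 (1.76 ± 0.37) and probe14097 (-0.86 ± 0.20), each as 10 µM minus 5 µM. The 2 probes of Atat1 differed in their values. None of the 20 lists differed between the doses, with adjusted p from 0.830 to 0.840. The median, the mean and the test differed in sign for germline genes, extracellular matrix, adipocyte, blood and immune cells and oxidative stress.

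Both doses shared 20 features past the threshold, 17 higher and 3 lower at both, where independence would give 0.0886 and 0.0345, and 0 had opposite signs. The doses also share the estimate of the spread of each feature, so the numbers given for independence may be too low. Of the 157 features that passed at 10 µM, 153 had the same sign at 5 µM. Across all features, which are not independent replicates, Pearson's r between the doses was 0.0987 and Spearman's rho 0.110, against a mean r of 0.00256 in simulated data without effects. Both doses were set against untreated Erbb2 cells, and a part of the overlap that comes from that shared control cannot be separated.

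The fourth comparison asked what 10 µM changed in untransfected cells (n = 4), the control experiment. Egr1, an immediate early transcription factor (13653), rose by 2.73 ± 0.31, or 6.64-fold, Nfkbia, the inhibitor that holds NF-kappaB in the cytoplasm (18035), by 2.17 ± 0.22, and Mdm2, the ubiquitin ligase of p53 and itself a p53 target (17246), by 1.70 ± 0.18. Genes of the integrated stress and unfolded protein response fell, with a median of -0.79 over 22 members and 9 past the threshold, all lower. Among them were the endoplasmic reticulum chaperone Hspa5 (-1.68 ± 0.17), the pseudokinase Trib3 (-1.84 ± 0.38), asparagine synthetase Asns (-1.54 ± 0.34) and the amino acid transporter subunit Slc3a2 (-1.52 ± 0.17). Genes of oxidative stress and metallothionein fell, with a median of -0.81 over 21 members and 10 past the threshold, including the ferritin chains Ftl1 (-1.27 ± 0.14) and Fth1 (-1.05 ± 0.17), metallothionein Mt1 (-1.12 ± 0.22) and glutathione transferase Gstp1 (-1.08 ± 0.25).

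In limma, 339 features passed, 74 higher and 265 lower, and 207 carried a gene symbol, 34 higher and 173 lower. With the treated RNA taken to be in the other dye, the same 339 features passed, 265 higher and 74 lower. Ribosomal protein genes fell with a median of -0.60 and 21 of 53 past the threshold, among them Rps4x (-1.27 ± 0.17), Rps27 (-1.13 ± 0.14), Rpl5 (-1.10 ± 0.15) and Rps14 (-1.07 ± 0.13). Glycolysis and hypoxia fell with a median of -0.49 and 6 of 20 past the threshold, including the mutase Pgam1 (-1.58 ± 0.24), Aldoa (-1.09 ± 0.14), the angiogenic factor Vegfa (-1.01 ± 0.23) and Ero1a, an oxidase of the endoplasmic reticulum (-2.68 ± 0.65). Interferon response genes rose with a median of 0.62 over 15 members, and Ifit3 (2.22 ± 0.51) and Bst2 (1.45 ± 0.31) passed. Cell cycle genes rose with a median of 0.41, 27 of 33 members lay above 0, and Cks2, a cofactor of cyclin-dependent kinases (1.19 ± 0.18), passed. Epithelial genes had a median of 0.44 over 11 members, with keratin gene Krt8 past the threshold (1.13 ± 0.27).

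The adjusted p of these list shifts were 3.85e-18 for the stress response, 4.32e-14 for oxidative stress, 1.02e-39 for ribosomal proteins, 3.49e-07 for glycolysis, 0.000184 for interferon response and 5.79e-05 for cell cycle, and these 6 lists also passed with an estimated correlation. The epithelial list had an adjusted p of 0.0376, which became an adjusted p of 0.119 with an estimated correlation and was then lost. Without array 4 its median was -0.02 with an adjusted p of 0.413, and without array 2 it was 0.34 with an adjusted p of 0.0617. Adjusted over the list alone, 13 stress response genes, 11 oxidative stress genes, 35 ribosomal genes and 6 glycolysis genes were lower, and 3 interferon, 3 cell cycle and 2 epithelial genes were higher. The other 13 lists had adjusted p from 0.0553 to 0.728. Of these, extracellular matrix lay nearest the threshold, with 4 of 31 members lower, namely fibronectin Fn1 (-1.63 ± 0.20), the collagen chaperone Serpinh1 (-1.28 ± 0.29), lysyl oxidase Lox (-1.06 ± 0.18) and Col1a2 (-0.79 ± 0.19). The median, the mean and the test differed in sign for skeletal muscle, blood and immune cells and cholesterol synthesis.

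Further genes that rose were the tetraspanin Cd151 (2.59 ± 0.50, n = 3), Slc15a5, a member of the peptide transporter family (2.47 ± 0.17), Iffo1 (2.04 ± 0.35), the guanylate-binding protein gene Gbp8 (1.97 ± 0.47), Bcap31 (1.85 ± 0.42) and the ciliary transport gene Ift27 (1.82 ± 0.38, n = 3). Genes with the greatest fall were Guca2b, which encodes uroguanylin (-3.27 ± 0.55), monoamine oxidase Maoa (-2.89 ± 0.40), Arhgef17 (-2.79 ± 0.44, n = 3), Osbpl6 (-2.57 ± 0.36, n = 3), Ddx52 (-2.54 ± 0.59, n = 3), Dcdc2c (-2.31 ± 0.32, n = 3), Ift88 (-2.26 ± 0.41, n = 3), Ccdc89 (-2.24 ± 0.52, n = 3) and Slc32a1 (-2.23 ± 0.39, n = 3). Guca2b had -5.07 and -4.63 on arrays 1 and 2, and -1.34 and -2.06 on arrays 3 and 4 with the dyes exchanged. On array 1 Guca2b and Arhgef17 had the same value, -5.072. Signal over background is unknown, so values near the floor cannot be excluded for these genes. The methyl-CpG binding protein Mbd2 fell by 1.12 ± 0.20 and was the 1 of 10 DNA methylation machinery genes that passed. Apaf1 (-0.80 ± 0.14), Atf4 (-0.89 ± 0.13), Pkm (-0.76 ± 0.18), Gapdh (-0.81 ± 0.15), the muscle light chain Mylpf (-0.78 ± 0.15) and the immune adaptor Tyrobp (-0.68 ± 0.16) also fell. Dnmt1 (-0.11 ± 0.14), Cdkn1a (0.37 ± 0.65), B2m (0.13 ± 0.24) and Tap1 (1.01 ± 0.41) did not pass. The count was 222 without array 1 and 213 without array 2, and the group fitted on its own 4 arrays gave 0 features.

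**Figure D2:**
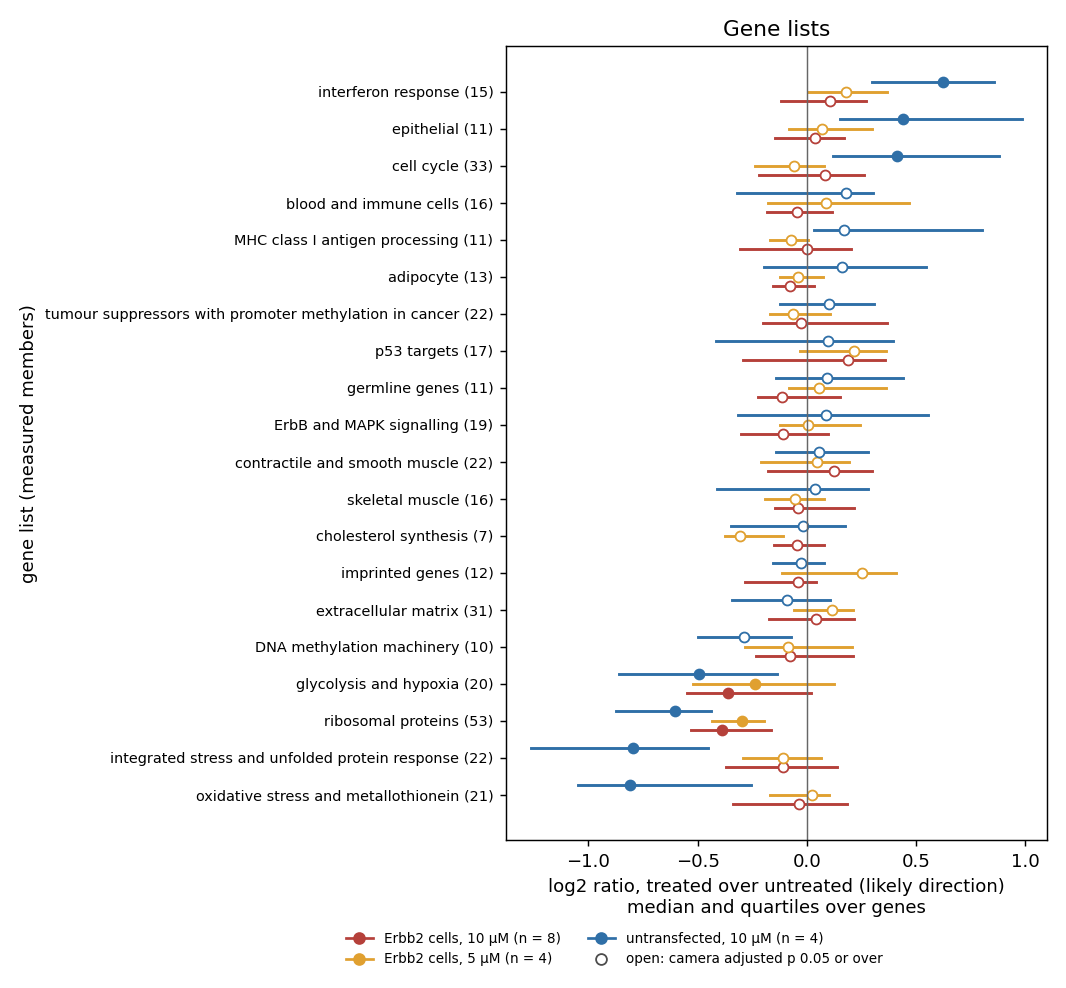
Median (dot) and quartiles (line) of the fitted log2 ratios, treated over untreated in the likely direction, over the measured members of 20 gene lists in the 3 groups, with the number of members in parentheses and filled dots for an adjusted p under 0.05. Ribosomal proteins lie below 0 in all 3 groups, at -0.39, -0.30 and -0.60, and the stress lists lie at -0.79 and -0.81 in untransfected cells.

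The fifth comparison asked whether 10 µM acted differently in Erbb2-transfected and untransfected cells, by testing the difference between the responses. The response of Ero1a was higher in Erbb2 cells by 4.20 ± 0.82, that of Guca2b by 3.60 ± 0.69, Maoa by 3.10 ± 0.52, Ift88 by 2.91 ± 0.49 and Arhgef17 by 2.61 ± 0.52. The responses of Egr1 (-3.48 ± 0.39), Slc15a5 (-2.22 ± 0.21), Mdm2 (-2.13 ± 0.22), Iffo1 (-2.11 ± 0.43) and Nfkbia (-1.87 ± 0.28) were lower in Erbb2 cells. Of these 10 genes, Egr1, Slc15a5, Mdm2 and Nfkbia passed whichever array was left out, and the other 6 did not. Genes of the stress response had a median difference of 0.68, with all 22 members higher in Erbb2 cells and 2 past the threshold, Hspa5 (1.19 ± 0.21) and Slc3a2 (1.28 ± 0.21). Oxidative stress genes had a median difference of 0.63, with 4 of 21 past the threshold, among them Gstp1 (1.53 ± 0.30) and Fth1 (1.18 ± 0.21).

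In limma, 101 features differed, 78 higher and 23 lower in Erbb2 cells, and 66 carried a gene symbol. The stress response list had an adjusted p of 1.59e-10 and the oxidative stress list 1.10e-09. Ribosomal genes differed by a median of 0.29 with 46 of 53 members higher in Erbb2 cells, 0 past the threshold alone and an adjusted p of 2.43e-07. Interferon genes differed by -0.54 (adjusted p 0.0149, 0 past the threshold) and cell cycle genes by -0.35 (adjusted p 0.00114, 1 past the threshold, Cks2). These 5 lists also passed with an estimated correlation. With only probes that had a value on all arrays, the interferon list of 8 members differed by -0.29 and its call was lost (adjusted p 0.0921). Adjusted over the list alone, 12 stress response, 9 oxidative stress and 2 ribosomal genes were higher in Erbb2 cells, and 2 interferon and 3 cell cycle genes were lower.

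For 3 more lists the call was lost with an estimated correlation. Extracellular matrix differed by 0.28 (1 of 31 past the threshold, Fn1 at 1.68 ± 0.25), with an adjusted p of 0.0279 and an adjusted p of 0.0559 with an estimated correlation. Glycolysis and hypoxia differed by 0.13 (1 past the threshold, Ero1a), with an adjusted p of 0.0404 and an adjusted p of 0.0906 with an estimated correlation. ErbB and MAPK signalling differed by -0.14 (1 past the threshold, Egr1), with an adjusted p of 0.0483 and an adjusted p of 0.0559 with an estimated correlation. Without untransfected array 1 each of the 3 had an adjusted p of 0.0667. The other 12 lists had adjusted p from 0.0537 to 0.966, and the median, the mean and the test differed in sign for imprinted genes, p53 targets, blood and immune cells and cholesterol synthesis.

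At 10 µM the lines shared 90 features past the threshold. Of these, 71 were lower in both lines, where independence would give 2.28, and 8 were higher in both, where it would give 0.298. The other 11 were higher in Erbb2 cells and lower in untransfected cells, where it would give 1.07, and 0 were the other way round. Because the groups share the estimate of the spread of each feature, calls in both lines are not independent. The numbers given for independence may therefore be too low. Among the 11 were Apaf1, Hoxb1, Hyi, Lhfpl2, Psap and App, and their responses differed by between 1.73 and 2.08 on the log2 scale. Of the 90 shared features, 78 had the greater size in untransfected cells. The median standard error over all features was 0.3606 there (n = 4), against 0.2597 in Erbb2 cells (n = 8). A feature thus needed a greater size to pass in untransfected cells, so this count cannot tell whether they responded more strongly. Cd5, at 0.12 ± 0.14 in untransfected cells, differed between the lines by 1.17 ± 0.17.

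With the treated RNA of the untransfected arrays taken to be in the other dye, 351 features differed between the lines, 72 higher and 279 lower in Erbb2 cells, and 53 of them were among the 101. The count was 67, 63 and 60 without untransfected array 1, 2 or 4, 41 when only these groups were fitted, and 0 with the replicate number as a block. With the arrays turned, the 90 shared features split by construction into 79 of opposite sign, 71 lower and 8 higher in Erbb2 cells, and 11 higher in both lines.

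**Figure D3:**
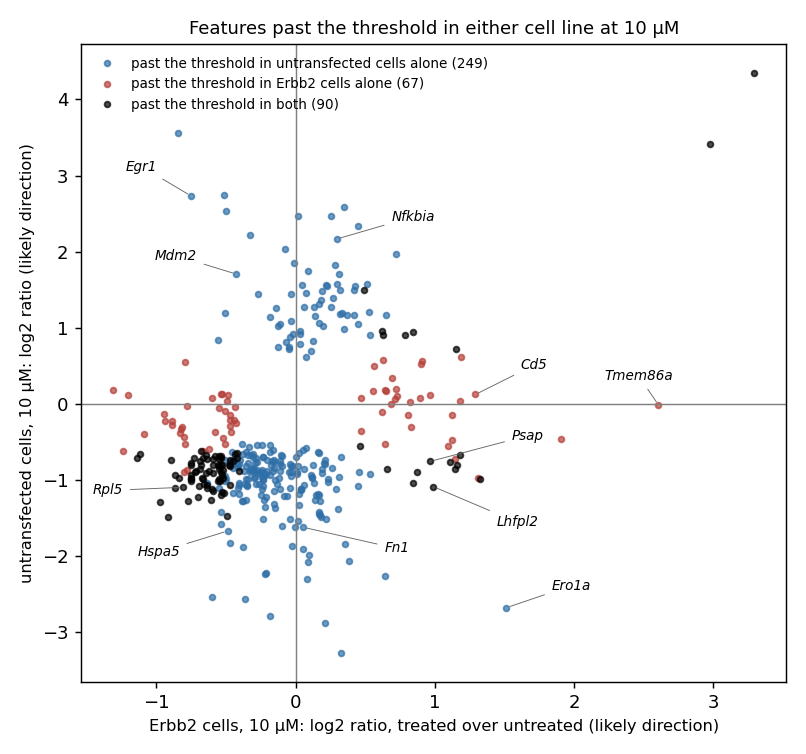
Fitted log2 ratio, treated over untreated in the likely direction, in Erbb2 cells (horizontal axis, n = 8) and in untransfected cells (vertical axis, n = 4) at 10 µM for the 406 features past the threshold in either line. The 90 features past it in both lines (black) lie mostly in the lower left, 249 passed in untransfected cells alone (blue) and 67 in Erbb2 cells alone (red).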

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

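Tests chosen after their results were seen were those of a dye bias equal on every array, of an abundance bias in Erbb2 cells alone and as the whole cause in untransfected cells, of one cDNA on several spots including the comparison with probes of one gene, of a smaller measurement error in the untransfected arrays, and those with the untransfected arrays turned, and the others were fixed before.

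The drug acted differently in the 2 cell lines for 101 features, by a test of the difference itself, and the named genes among them follow as Erbb2 minus untransfected cells on the log2 scale. The response was higher in Erbb2 cells for Ero1a (4.20), Guca2b (3.60), Maoa (3.10), Ift88 (2.91), Arhgef17 (2.61), Dcdc2c (2.39), Osbpl6 (2.20), Lhfpl2 (2.08), Apaf1 (1.96), Hyi (1.87), Hoxb1 (1.85), App (1.78), Psap (1.73), Fn1 (1.68), Gstp1 (1.53), Slc3a2 (1.28), Hspa5 (1.19), Fth1 (1.18), Cd5 (1.17), Cp (1.14) and Ftl1 (0.90). It was lower for Egr1 (-3.48), Slc15a5 (-2.22), Mdm2 (-2.13), Iffo1 (-2.11), Nfkbia (-1.87), Cks2 (-1.69) and the unnamed probe14097 (-1.66). Lists that differed were integrated stress and unfolded protein response (0.68), oxidative stress and metallothionein (0.63), ribosomal proteins (0.29), extracellular matrix (0.28), glycolysis and hypoxia (0.13), interferon response (-0.54), cell cycle (-0.35) and ErbB and MAPK signalling (-0.14), and the calls of extracellular matrix, glycolysis and ErbB were lost with an estimated correlation (adjusted p 0.0559, 0.0906 and 0.0559). With the untransfected arrays turned, 84 of the 101 features had the other sign. The real split gave 101 features and the highest of the other splits drawn gave 1, so that 1 of 100 splits was as large. This argues against a chance split of independent arrays, but the labels do not show that the arrays are independent. Splits that mix the lines also carry the responses into the spread, which lowers their counts. Between the doses 0 features differed, so all 100 splits gave at least as many by construction and the test decides nothing there. The highest other split gave 4.

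Against sign patterns of the arrays, the real 157 features in Erbb2 cells at 10 µM compare with at most 1 in the others, so that 1 of 100 patterns was as large. This argues against chance signs on independent arrays, and whether the arrays are independent is not in the labels. In Erbb2 cells at 5 µM and in untransfected cells the 8 possible patterns are too few for a share under 0.05. The real counts there were 26 and 339, and the highest of the other patterns were 0 and 6.

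Single arrays far from the others of their group were found in 6 of 121 tests, where chance gives 6.05. They were Rps16 on array 6 (-2.31, nearest -0.92) and Eef2 on array 3 (-2.12, nearest -1.04) of Erbb2 cells at 10 µM. At 5 µM they were Cdkn1a on array 4 (1.69, nearest -0.38) and B2m on array 1 (0.18, nearest 1.12). In untransfected cells they were Ifit3 on array 2 (3.09, nearest 1.95) and Gbp8 on array 4 (3.92, nearest 1.58).

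In both lines at 10 µM, 71 features fell, 14 of them ribosomal and 3 glycolysis genes, and 8 rose, while with the untransfected arrays turned these 79 had opposite signs. With as many arrays in either dye, a dye bias cancels in the group means unless the deposited values were already turned. In that case, under a bias particular to single probes, values as deposited should correlate between 2 probes of a gene at least as well as turned values. Over 1879 genes the turned values correlated better, by 0.0829 ± 0.0310 in Erbb2 cells and 0.146 ± 0.0320 in untransfected cells (bootstrap SE). This argues against a bias particular to single probes. A bias shared by the probes of a gene would also make turned values correlate better, so the test cannot decide on it in either line. A bias that grows with abundance is argued against in Erbb2 cells, where 37 other abundant transcripts had a median of 0.08 and lay 0.465 ± 0.126 above the ribosomal list, and as the whole cause in untransfected cells, where they lay 0.418 ± 0.0987 above it. For a part of the fall in untransfected cells, where they had -0.187 (camera p 0.00316), it cannot be told apart, because a bias shared by the probes of a gene would escape the test of probe pairs were the values already turned, and a drug response common to both lines stays open as the biological explanation.

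The 11 features that rose in Erbb2 cells and fell in untransfected cells were Apaf1, App, Grn, Hoxb1, Hyi, Lhfpl2, Npc2, Psap, Slk and the unnamed probe12884 and probe17337, some of them named after their values were seen, and with the untransfected arrays turned all 11 rose in both lines. Dye bias of the probes equal on every array would, with the dye labels as read, leave no feature differing between the lines, and 101 differed. One cDNA on several spots is a candidate explanation, but their array-to-array deviations correlated by a median of -0.0440 and those of probes of one gene by -0.0747 over 47 genes, so the test had no power and the explanation cannot be told apart from a shared response. Psap, Grn and Npc2 are lysosomal. As predicted if lysosomal genes moved as a class, 37 others, chosen without called members, were higher in Erbb2 than in untransfected cells by a median of 0.358 (camera p 3.93e-05). With the untransfected arrays turned the difference was -0.063 (camera p 0.887). Other abundant transcripts were also higher in Erbb2 cells, by 0.232 (camera p 0.00166). Of the fixed lists, 5 differed in that direction and 3 in the other. A move of lysosomal genes as a class thus cannot be told apart from a wider difference between the lines. With the labels as read either may account for those 3 genes, and Hoxb1, Apaf1, Hyi and the rest are left without a tested explanation.

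Genes of the integrated stress response were lower in untransfected cells, where 9 of 22 passed, against 1 in Erbb2 cells. A smaller measurement error in the untransfected arrays would give more calls without a difference in the values, but the values themselves differed by a median of 0.684 with an adjusted p of 1.59e-10, which argues against it. The dye labels of the untransfected arrays stay open, and with their sign turned the median difference became -1.05. A difference between the lines that comes with Erbb2 stays open and untested, since 1 transfected line was compared with 1 untransfected line.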

How the results depend on the processing

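Keeping the placeholder values, leaving out the 3 widest arrays and turning the untransfected arrays were chosen after the data were examined, and the other settings before. Except with values as deposited and with the untransfected arrays turned, which turned every sign of that group and most differences between the lines, 0 of the named genes and 0 of the list shifts past the threshold changed direction under any setting, save that the median of the epithelial list was -0.02 without untransfected array 4, the direction of its test staying. The doses differed in 0 features under every setting, with 7148 to 15295 features tested. Leaving out 1 array at a time gave 103 to 142 features in Erbb2 cells at 10 µM, 5 to 6 at 5 µM, 213 to 259 in untransfected cells, 0 to 0 between the doses, 60 to 105 between the lines and 10 to 12 list shifts in the treated groups, against 11 with all arrays. Of the genes named for each, 20 of 28 at 10 µM, 1 of 13 at 5 µM, 26 of 46 in untransfected cells and 4 of 10 between the lines passed in each of those fits. Signal over background is not in the files, so what it limits is unknown.

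Counts that moved by over 1.5 times follow, in the order Erbb2 10 µM, Erbb2 5 µM, untransfected and difference between the lines where several are given, and except where stated the cause was not tested. Scaling gave 46 at 5 µM (34 higher, 12 lower), array weights 96 (59 higher, 37 lower), single probes 16 and a dye term per group 9. Probes with a value on all arrays, where fewer features are tested, gave 247, 73 (44 higher, 29 lower) and, between the lines, 189. A filter of 2 values per group, where more are tested, gave 98 and 4. Fits on the groups of a comparison alone, which estimate the spread from fewer arrays, gave 22 (15 higher, 7 lower), 0, 0 and 41. An adjusted p under 0.01, stricter by construction, gave 75, 4, 177 and 40, and a test against a 1.2-fold change 33 (21 higher, 12 lower), 4, 154 and 45. Without arrays 3, 5 and 6 of Erbb2 cells at 10 µM, which leaves 5 arrays, that group gave 57 (27 higher, 30 lower). With the replicate number as a block the lines differed in 0 features. Deviations from the group means had r between arrays of one number from -0.0281 to 0.0383 over 10 pairs. That cannot decide whether the numbers pair the samples, since deviations of probes of one gene did not correlate either, with a median of -0.0747. The count of 0 therefore stays a limit on the difference between the lines. An estimated correlation left 9 of the 11 list shifts. Turning the untransfected arrays gave 351 between the lines and changed the shared features of one sign from 79 to 11.

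Values as deposited, which set exchanged arrays against each other, gave 2, 0, 4 and 0 features and 0 list shifts. With them the sign turned at 10 µM for Tmem86a (-1.71), Cd5 (-0.16), Hyi (-0.21), Psap (-0.062), Agrn (-0.0021), Ctdspl2 (0.10), Akr1c18 (0.19), Klhl21 (0.091), Dnaja1 (0.21), Rps16 (0.14), Pgm1 (0.16), Sparc (-0.22), Aldoa (0.23), Pkm (0.21), Rps14 (0.043) and the glycolysis list (0.0067), and the median alone turned for the ribosomal list (0.0069). At 5 µM it turned for Cd5 (-0.17), Znf41-ps (-0.22), Hoxb1 (-0.18), Psap (-0.059), Hyi (-0.18), Haus4 (-0.034), Ephb1 (0.72), Aldoa (0.20) and the glycolysis list (0.14). In untransfected cells it turned for Cd151 (-1.92), Iffo1 (-0.39), Gbp8 (-0.57), Bcap31 (-1.25), Ift27 (-0.15), Mdm2 (-0.035), Maoa (0.15), Ero1a (1.13), Ddx52 (1.19), Ift88 (0.15), Cks2 (-0.035), Slc3a2 (0.19), Fn1 (0.017), Gstp1 (0.015), Fth1 (0.022) and Rps14 (0.034), and the direction of the test turned for the interferon (median 0.070), epithelial (0.011) and oxidative stress (-0.014) lists. Between the lines it turned for Ero1a (-1.32), Maoa (-0.85), Ift88 (-0.43), Slc15a5 (0.23), Mdm2 (0.058) and the test of the ErbB list (-0.0010), and the median alone for the extracellular matrix list (-0.035).

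With the untransfected arrays turned, which changes that group by its sign alone, the difference between the lines turned for 84 of the 101 features. Among the named ones these were Ero1a (-1.17), Guca2b (-2.95), Maoa (-2.68), Ift88 (-1.62), Arhgef17 (-2.97), Egr1 (1.98), Slc15a5 (2.72), Mdm2 (1.28), Iffo1 (1.96), Nfkbia (2.46), Dcdc2c (-2.23), Osbpl6 (-2.93), Lhfpl2 (-0.10), App (-0.032), Fn1 (-1.57), Gstp1 (-0.64), Slc3a2 (-1.75), Hspa5 (-2.16), Fth1 (-0.92), Ftl1 (-1.65), Cks2 (0.69) and the unnamed probe14097 (1.84). Apaf1 (0.35), Hyi (0.34), Hoxb1 (0.51), Psap (0.21) and Cp (0.52) kept their sign and no longer passed, and Cd5 (1.41) passed. The lists turned too, namely interferon response (0.91), cell cycle (0.54), integrated stress (-1.05), ErbB (0.034), oxidative stress (-0.92), glycolysis (-1.12) and ribosomal proteins (-0.92). For extracellular matrix the direction of the test turned, while the median (0.024) kept its sign. The added lists turned as well, namely lysosomal genes (-0.063), synthetases (-0.365), translation factors (-0.593), chaperones (-0.421) and other abundant transcripts (-0.095).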

Other observations

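Gene classes outside the fixed lists were written down and tested after the main results were seen, as were the genes named here and the turning of the untransfected arrays. The lysosomal test and the test of abundant transcripts over both lines alone had their bounds fixed before their values. The tests of abundant transcripts in a single line did not. Translation factors fell in untransfected cells, with a median of -0.455 over 31 measured members and an adjusted p of 2.45e-12 over the 5 added lists. Of these 7 passed alone, among them the elongation factor subunits Eef1b2 (-1.23 ± 0.14, n = 4) and Eef1a1 (-0.87 ± 0.19) and the poly(A)-binding protein Pabpc1 (-0.70 ± 0.13). They also fell in Erbb2 cells, with a median of -0.26 at 10 µM (adjusted p 4.22e-07, with Eef1b2, Eef2 and Tpt1 past the threshold) and -0.19 at 5 µM (adjusted p 0.00318, with 0 past it). The fall was deeper in untransfected cells by a median of 0.20 (adjusted p 0.00201), but with the untransfected arrays turned they rose there and the difference was -0.593 (adjusted p 8.41e-16). Aminoacyl-tRNA synthetases, which load amino acids onto transfer RNAs, fell in untransfected cells with a median of -0.366, 0 of 15 members above 0 and Eprs (-1.42 ± 0.15) and Yars (-1.38 ± 0.29) past the threshold (adjusted p 1.70e-05). In Erbb2 cells at 10 µM their median was 0.02 (adjusted p 0.867), and the difference between the lines had a median of 0.38 (adjusted p 9.82e-05), or -0.365 with those arrays turned (adjusted p 0.00153).

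Chaperones, which fold new proteins, fell in untransfected cells with a median of -0.336 over 24 members (adjusted p 0.00414). Hspd1 (-1.27 ± 0.15) and Tcp1 (-0.68 ± 0.15) passed the threshold. The list was written as cytosolic, but Hspd1 is the chaperonin of mitochondria. In Erbb2 cells at 10 µM the median of the list was -0.20 (adjusted p 0.0068), with Dnaja1 and St13 past the threshold. The lines did not differ past it (median 0.07, adjusted p 0.374), whereas with the untransfected arrays turned they did (-0.421, adjusted p 0.000544). The 37 lysosomal genes had a median of 0.14 in Erbb2 cells at 10 µM (adjusted p 0.00391) and -0.16 in untransfected cells (adjusted p 0.0186). The list of 37 other abundant transcripts had 0.08 and -0.19, and it differed between the lines by 0.23 (adjusted p 0.00207, or 0.0167 with an estimated correlation). With the labels as read, the difference was thus not particular to the protein synthesis classes. With the untransfected arrays turned this list differed by -0.095 and did not pass (adjusted p 0.0796), so that statement does not hold there. Lower values of ribosomal proteins, translation factors, synthetases and chaperones in untransfected cells may reflect a lower output of the protein synthesis machinery, a reading formed from these same values and not tested independently. The doubtful dye labels of those arrays stay open for these classes as well.

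Probes without a gene symbol also gave high values in all 3 groups. The unnamed probe9740 had 3.29 ± 0.12 in Erbb2 cells at 10 µM (n = 8), 3.61 ± 0.17 at 5 µM (n = 4) and 4.34 ± 0.17 in untransfected cells (n = 4). It differed between the lines by -1.05 (adjusted p 0.0261 from limma), or by 7.64 with the untransfected arrays turned. The unnamed probe7407 had 2.98 ± 0.15, 3.44 ± 0.21 and 3.42 ± 0.21. Both passed in each group and were chosen after their values were seen. With the untransfected arrays turned, both have the other sign in that group.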
